A study of Mus musculus with 8 samples.

How the data were processed

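RNA of 6 tNT lines and 2 NT lines was hybridised to Illumina bead arrays as biotin-labelled cRNA, 1 array per line. The deposited table holds a bead intensity per probe and array on a linear scale, not background-subtracted as its values show, and beside each a detection p-value, per the file headers, which is low where a probe is above the negative controls. A second table holds the authors' processed values of the same arrays on a log2 scale. Its 8 columns have the same distribution, with a median of 3.49 each, and rank the probes of each array as the intensities do (Spearman correlation of 1). The submitters' processing notes name BeadStudio 3.2, RMA and lumi, with no role or order, so which step each did stays unknown, and the background step behind the processed values is not given in the sources used here. Columns were matched to lines by their names, and no column of per-sample values was left out.

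Intensities were background-corrected and quantile normalized with neqc in limma 3.58.1 (R 4.3.3), which infers the background from the detection p-values, with an offset of 16, and are on the log2 scale. Quantile normalization sets all arrays to 1 distribution, so a difference in total RNA per cell between tetraploid and other cells is not measured. A gene was tested if a probe had a detection p under 0.01 on at least 2 of the 8 arrays, and was represented by its brightest probe by the mean over all arrays. The platform annotation gives 23978 probes 1 gene each, none several, and leaves 1719 unnamed. Symbols were updated through gene identifiers of a RefSeq table of assembly GRCm38.p6, where 23962 probes matched. That table was used for names, chromosome membership and gene order only, since no build is named for the array, and no coordinates are given. Of the 8816 tested, 8150 have a name and 666 do not.

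Groups were compared with lmFit and eBayes in limma, with 2-sided tests, with Benjamini-Hochberg adjustment and a threshold of 0.05. Passage was fitted as a slope over the 6 tNT lines. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, over 21 of 23 lists with at least 5 detected members. Where a gene was above background on no array of a group, the fold is a bound against the higher of its own value and the lowest detected value on each array, as means of normalized log2 values. Chromosome shifts per line are medians of deviations from each gene's median over the 8 arrays, set against 10000 random lists matched on expression in 10 bins (Python 3.11.15, numpy 2.4.6, pandas 2.3.3). No 2 arrays were copies of each other, since a pair shared exactly equal intensities for at most 1 of the 25697 probes. The nearest tNT pair and the NT pair had correlations of 0.993, and each line was counted once. The labels do not say that the RNA came from separate cultures beyond the line numbers.

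The groups, tests, lists and the rule for named genes were fixed before the data were examined. The rule took the 12 largest increases and the 12 largest decreases among genes past the threshold whose tNT values lay on one side of both NT values, the 6 genes of smallest p per direction of passage, the 20 with the largest SD among tNT lines, up to 4 members of smallest p per list, and 12 genes fixed by name. Rhox6, Rhox9, Zfp330, Arl3 and the other genes named for their other probes were chosen after their values were seen. Alternatives covered 4 other normalizations, detection filters, every probe, the variance model, array weights, leaving out each line, a block by line number, passage ranges and, added later, leaving out lines or chromosomes. A block by BeadChip was not run, since the column names give no chip.

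The fits were tested on simulated data before use. Of 100 simulated genes with a 2-fold difference between tNT and NT lines among 8816, 76 were called, and of 100 with a 4-fold difference 92, with 10 false calls. For passage, 29 of 100 with a 2-fold change over the passage range were called and 88 of 100 with a 4-fold change, with 9 false calls. A simulated shift of 0.2 of a chromosome in 1 line among 8145 genes was recovered as 0.17 and called, with 0 other pairs called. The simulated noise was independent between genes, so these counts do not measure false calls from genes that vary together. Figures were drawn with matplotlib 3.10.9.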

Results

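Total RNA of 8 mouse embryonic stem cell lines was measured on Illumina bead arrays, with 1 array per line. Of these, 6 lines came from tetraploid nuclear transfer (tNT lines, labelled tetraploid) and 2 from nuclear transfer (NT lines, labelled not tetraploid). Nuclear transfer places a somatic nucleus in an egg whose own nucleus was removed, and the series title refers to 2 somatic nuclei reprogrammed in the same egg cytoplasm. The design text gives the tNT lines 1 to 6 the numbers 17, 19, 25, 29, 18 and 25, read here as passage, the number of times a culture was split, and gives no such number for the NT lines. All lines are labelled as mixed strain. Between 10449 and 10969 of the 25697 probes were above background on an array, and 8816 genes or unnamed probes entered the tests. Precision is limited by the number of arrays, 6 against 2, and p-values measure the spread between these lines only.

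The main question of the design is how tNT lines differ from NT lines. Among the genes lower in tNT lines were Fgf8, Fgf5, Krt18 and Krt8, and among those higher were Dazl and Pramel39. Fgf8, a growth factor of the primitive streak, had a normalized log2 intensity of 5.13 ± 0.43 (SD, n = 6) in tNT lines and 8.77 ± 0.41 (SD, n = 2) in NT lines, a 12.4-fold difference (limma, adjusted p = 8.85e-04), and was above background on only 1 of the 6 tNT arrays. Fgf5, the growth factor that marks primed epiblast, was 5.73-fold lower (adjusted p = 0.0176) and above background on 2 of the 6 tNT arrays. The epithelial keratins Krt18 and Krt8 were 4.28-fold and 3.84-fold lower (adjusted p = 0.00464 and 0.00505). Dazl, an RNA-binding protein of germ cells, was 2.93-fold higher (adjusted p = 0.0346) and Pramel39 was 3.43-fold higher (adjusted p = 0.0176).

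In all, 164 of the 8816 passed an adjusted p of 0.05 in limma's moderated test, 79 higher and 85 lower in tNT lines, and 150 of the 164 have a gene name. In each of the 164 all 6 tNT values lay on one side of both NT values. This also held for 1913 of all 8816, where chance gives 7.14%. At an unadjusted p under 0.05 there were 1583, against 440.8 expected by chance. By the brightest probe of each gene, the remaining genes with the largest increases were Zfp869 (3.78-fold), Aqp9, a water and glycerol channel (3.32-fold), Tex19.2 (3.31-fold), Mageb4 (3.31-fold), Ezhip, an inhibitor of the Polycomb complex PRC2 (3.25-fold), Gm428 (1.68 on the log2 scale), Gm16367 (2.97-fold) and Pramel37 (2.90-fold), with adjusted p between 0.00505 and 0.0350. Ccdc172 and Ott were not above background on either NT array and were at least 2.98-fold and at least 2.28-fold higher in tNT lines. The remaining genes with the largest decreases were Chst1 (5.37-fold), Dok2 (3.88-fold), Npas4 (3.28-fold), Actc1, cardiac actin (3.02-fold), and Wnt8a (2.99-fold), with adjusted p between 0.00400 and 0.0364. Of the 6 tNT arrays, Chst1 was above background on 2, and Npas4, Actc1 and Wnt8a on 1, so the folds of these genes and of Fgf8 and Fgf5 rest mostly on tNT values not above background. Ppp4r4, Dgkk and Pkdcc were not above background on any tNT array and were at least 2.37-fold, at least 2.03-fold and at least 2.33-fold lower there.

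**Figure D1:**
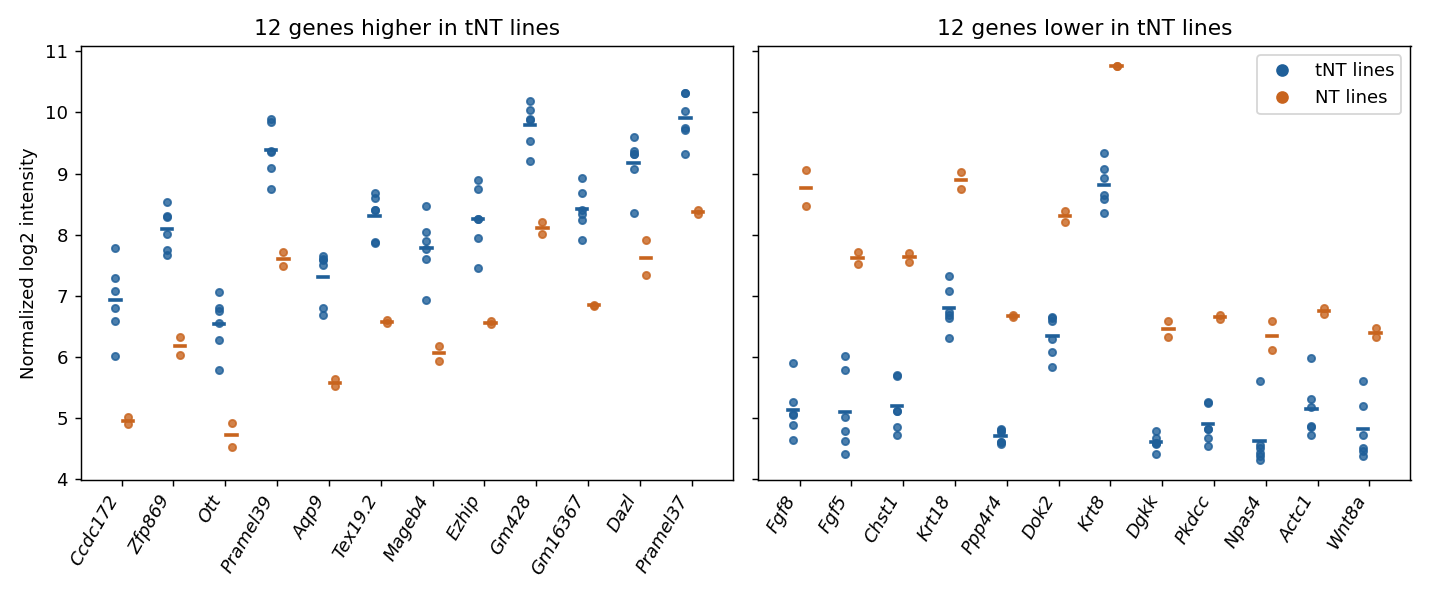
Normalized log2 intensity (vertical axis) of the 12 genes with the largest increase and the 12 with the largest decrease in tNT lines (horizontal axis). Each point is a line, blue for the 6 tNT lines and orange for the 2 NT lines, and bars are group means. All tNT points lie on one side of both NT points, with the widest gap in Fgf8, 5.13 against 8.77.

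The count depended on which lines entered. Without NT line 1 it was 6 and without NT line 2 it was 7, all lower in tNT lines, while it was 582 without tNT line 2 and 92, 93, 97, 80 and 85 without tNT lines 1, 3, 4, 5 and 6. Array weights gave 1381, tNT lines at passage 17 to 19 gave 27, those at passage 25 to 29 gave 213, and, chosen after the data were seen, leaving out tNT lines 4 to 6 gave 50, lines 1 to 3 gave 1044 and lines 2 and 3 gave 631.

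Of the 21 gene lists with at least 5 detected members, 7 were shifted between the groups by camera with its preset correlation. None of the 7 passed with an estimated correlation. Of the 18 members of the mesoderm and primitive streak list with a probe, 7 were measured. All 7 had lower values in tNT lines, with a median log2 difference of -0.74 (adjusted p = 4.29e-06, and adjusted p = 0.0735 with an estimated correlation). Among them 3 passed over all genes and 5 when adjusted over the list alone. Besides Fgf8, these included the transcription factor Lhx1 and the signalling protein Wnt3a, which were not above background on any tNT array and were at least 1.61-fold and at least 1.49-fold lower. Fgf8, Lhx1, Wnt3a and, in the next list, Wnt8a entered the tests only through the 2 NT arrays. For such genes the detection filter itself favours lower values in tNT lines. Of the primed epiblast list, 11 of 12 members had lower values, with a median of -0.66 (adjusted p = 1.9e-05, and adjusted p = 0.190 with an estimated correlation). Fgf5, Krt18 and Wnt8a passed over all genes, and 5 members passed when adjusted over the list alone. Cldn6, a tight junction protein, had a log2 difference of -1.13 and did not pass over all genes (adjusted p = 0.0618). Of the trophoblast list, 9 of 12 members had lower values (median -0.39, adjusted p = 0.00785, and adjusted p = 0.190 with an estimated correlation). Krt8 alone passed over all genes, and 2 members, Krt8 and Krt19, passed when adjusted over the list alone. Krt19 was not above background on any tNT array, so it also entered the tests only through the 2 NT arrays. This list was no longer past the threshold with genes detected on all 8 arrays (adjusted p = 0.234) or, chosen after the data were seen, without tNT lines 2 and 3 (0.0526) or 1 to 3 (0.115).

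The actin cytoskeleton list was also lower by camera, with lower values for 14 of 15 members and a median of -0.28 (adjusted p = 5.8e-05, and adjusted p = 0.0735 with an estimated correlation). The actin-binding proteins Tpm1 and Cnn2 were 2.45-fold and 2.36-fold lower (adjusted p = 0.0146 and 0.0109), and 3 members passed when adjusted over the list alone.

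The lists higher in tNT lines by camera hold genes of the early embryo, the germ line and glycolysis. All 7 measured members of the 2-cell-like list, named for the cleavage-stage embryo, had higher values (median 0.93, adjusted p = 4.88e-04, and adjusted p = 0.190 with an estimated correlation). Tmem92 and Tcstv1 passed over all genes, at 2.29-fold and 2.10-fold, and 4 members passed when adjusted over the list alone. Among the 4, Usp17la was above background on 5 tNT arrays and on neither NT array. For that gene the detection filter favours higher values in tNT lines. Of the methylation-sensitive germ line list, 10 of 14 members had higher values (median 0.90, adjusted p = 0.00305, and adjusted p = 0.190 with an estimated correlation). Dazl, Asz1 (2.66-fold) and Sohlh2 (2.16-fold, above background on 1 NT array), which act in germ cells, passed over all genes. Adjusted over the list alone, 7 were higher and 2 were lower. The lower pair were Rhox6 and Rhox9, homeobox genes of the X chromosome, with log2 differences of -2.21 and -1.92 that did not pass over all genes. The mean deviation of the list was -0.31 in tNT line 3 and -0.16 in tNT line 4, against -0.21 and -0.34 in the NT lines and 0.18 to 0.38 in the other tNT lines. The hypoxia and glycolysis list had higher values for 19 of 21 members (median 0.24, adjusted p = 0.00173, and adjusted p = 0.340 with an estimated correlation). None passed over all genes, and Pfkp, a phosphofructokinase, and Slc2a1, a glucose transporter, passed when adjusted over the list alone. In tNT line 2 the mean deviation of the list was -0.30, below both NT lines (-0.21 each), and without tNT lines 4 to 6, chosen after the data were seen, the call was lost (adjusted p = 0.0593), as it was by fry (adjusted p = 0.0642).

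The naive pluripotency list was not shifted (25 members, median 0.09, adjusted p = 0.342). Its members Pou5f1, Sox2, Nanog, Zfp42, Esrrb and Klf4 had log2 differences of -0.22, -0.06, 0.38, 0.14, 0.37 and 0.92, and none of these passed. Inside this list Lin28a, a regulator of let-7 microRNAs, was 2.32-fold lower (adjusted p = 0.00505) and Klf5 and Fbxo15 were higher by 0.59 and 0.57 on the log2 scale (adjusted p = 0.0301 and 0.0424). Markers of fibroblasts, which are often used as feeder cells, were not shifted between the groups (17 members, adjusted p = 0.758), and Col1a1 differed by 0.07 on the log2 scale (adjusted p = 0.927). Cdkn1a, a cell cycle inhibitor downstream of p53, differed by 0.21 (adjusted p = 0.423). Adjusted p-values of the other lists by camera with its preset correlation were 0.0543 for the mitotic spindle checkpoint, 0.0543 for cholesterol biosynthesis, 0.0651 for p53 targets, 0.276 for cumulus and granulosa markers, 0.276 for Hippo and Yap genes, 0.390 for imprinted genes, 0.431 for centrosome genes, 0.453 for neuroectoderm, 0.453 for stress and unfolded protein genes, 0.679 for DNA methylation enzymes, 0.758 for oxidative phosphorylation and 0.839 for endoderm. By fry, p53 targets (19 of 22 members higher) and cumulus and granulosa markers (4 of 5 higher) did pass (adjusted p = 0.0309 each). Neither passed by camera with an estimated correlation (adjusted p = 0.190 and 0.345). Among the imprinted genes Igf2 and Peg3 passed over all genes, at 2.69-fold and 2.30-fold lower in tNT lines (adjusted p = 0.0174 and 0.0436), and Peg3 was above background on 1 tNT array. The DNA methylation list had a negative median and mean while the fry test gave it the opposite direction, and its member Mbd1 was 2.13-fold higher (adjusted p = 0.00789). Xist was not above background on enough arrays to enter the tests, and the annotation used here names no probe for Meg3, H19 or Ddx3y. The Dlk1-Dio3 list and the sex-linked list had under 5 detected members and were not tested. Uty, a gene of the Y chromosome and the 1 measured member of the sex-linked list, was above background on 4 tNT arrays and on neither NT array. It was at least 1.11-fold higher in tNT lines and did not pass (limma, adjusted p = 0.0893). A difference in sex between the lines was not tested.

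Passage was compared within the 6 tNT lines as a slope. No gene passed (limma, smallest adjusted p = 0.994), and 391 had an unadjusted p under 0.05, against 440.8 expected by chance. The smallest p-values among genes with a positive slope belonged to Fbp1 (0.08 log2 units per passage), Nolc1 (0.07), Twf1 (0.06), Fgf4 (0.06), Nrn1l (0.07) and Arhgap18 (0.07), and among genes with a negative slope to Rarres2 (-0.09), Magea2 (-0.13), Prf1 (-0.08), Gm773 (-0.10), Pramel13 (-0.07) and Ddr1 (-0.09). Of the lists, the fibroblast markers were called lower at higher passage by camera with its preset correlation (adjusted p = 1.4e-06, and adjusted p = 0.701 with an estimated correlation). Slopes were negative for 16 of 17 members, with a median of -0.04 per passage. No member passed on its own, even when adjusted over the list alone. The mean deviation of these markers was 0.17, 0.57, -0.28, -0.23, -0.03 and -0.21 in tNT lines 1 to 6. Without each line in turn the fibroblast list stayed past the threshold, with a median of -0.06 without tNT line 5, but it did not pass by fry (adjusted p = 0.520). The primed epiblast list also had a negative median slope of -0.02 (adjusted p = 0.0344, and adjusted p = 0.701 with an estimated correlation), and lost the call without tNT lines 1, 2, 4 or 6 (adjusted p = 0.162, 0.131, 0.335 and 0.0568). It also did not pass by fry (adjusted p = 0.595), with the authors' values (0.0526) or with genes detected on all arrays (0.0688). Its median slope was -0.03 without tNT line 1, -0.03 without line 3 and -0.04 without line 5. No other list passed.

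The lines were compared with each other by the correlation of log2 values across genes, which are not independent replicates. The mean correlation was 0.981 within the tNT lines (15 pairs, 0.968 to 0.993), 0.993 between the NT lines and 0.976 between the groups (12 pairs, 0.973 to 0.981). Within-group correlations exceeded those between groups by 0.00572 (exact permutation test over 28 splits, one-sided p = 0.0714). The typical difference between 2 tNT lines was 1.66 times that between the NT lines, and 1 of 15 tNT pairs differed less than the NT pair. Tetraploid line 2 had the lowest mean correlation with its group, 0.973.

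Most of the 20 genes with the largest SD among tNT lines divided them into lines 1 to 3 and lines 4 to 6. The NT lines were on the side of lines 1 to 3. Across all tested genes lines 4 to 6 correlated with each other by 0.989, 0.989 and 0.993, but lines 1 to 3 did not form a set. Line 1 correlated by 0.987 with line 3 and 0.980 with line 2, against 0.985 and 0.986 with lines 5 and 6. Cops8, a subunit of the COP9 signalosome, had log2 intensities of 5.13, 5.19 and 4.57 in tNT lines 1 to 3, 9.83, 10.02 and 10.02 in lines 4 to 6, and 5.12 and 5.21 in the NT lines. Olig1, Atf4, Rgcc, Apoa2, Uap1, Tomm22, Esd and Gpx2 were likewise higher in each of lines 4 to 6 than on every other array, and 2210409E12Rik and Psmd8, a proteasome subunit, were lower in each of them. Psmd8 measured 10.19, 10.34 and 10.18 in lines 1 to 3 and 7.18, 7.33 and 6.95 in lines 4 to 6. Sox21 values in lines 4 to 6 also lay above those of all other arrays. The others of the 20 genes with the largest SD were Gbp2, Car4, Robo4, Lor, Egr4, Gbp2b, Gm14685 and Etv2, and line 2 had the highest tNT value in each of them except Egr4.

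**Figure D2:**
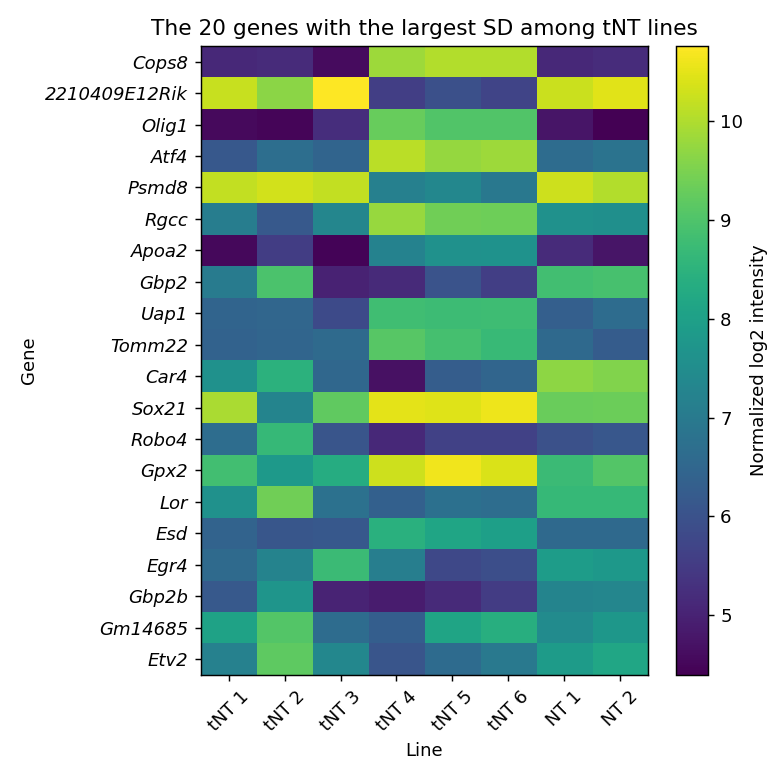
Normalized log2 intensity (colour scale) of the 20 genes with the largest SD among tNT lines (vertical axis) on each of the 8 arrays (horizontal axis). Cops8 stands near 10 in tNT lines 4 to 6 and near 5 on the other arrays, and Psmd8 shows the opposite pattern.

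Chromosomes were compared within each array as the median deviation of their genes. Of 160 pairs of line and chromosome, 9 were shifted by at least 0.1 on the log2 scale and past random gene lists matched on expression. Tetraploid line 2 had chromosome 2 at -0.19, chromosome 6 at 0.13 and chromosome 8 at 0.13. Tetraploid line 3 had chromosome 3 at -0.21, chromosome 10 at -0.12 and the X chromosome at -0.14. The X chromosome stood at 0.17 in line 1, -0.13 in line 4 and 0.11 in line 6. No chromosome reached that size in line 5 or in either NT line. By the random lists alone 67 of the 160 pairs passed, 17 of them in NT lines, so the calls rest on the size of 0.1. The X chromosome of line 5 (0.0909), that of NT line 2 (-0.0920) and chromosome 10 of line 2 (-0.0979) missed it narrowly. All 9 had an adjusted p of 9.7e-04, the smallest that 10000 draws gave here. These are descriptions of single arrays with no replicate. Between the groups, camera called chromosome 10 (median -0.11, adjusted p = 9.07e-05) and chromosome 17 (-0.09, adjusted p = 0.0214) lower and the X chromosome (0.10, adjusted p = 0.0289) higher in tNT lines, and none with an estimated correlation (adjusted p = 0.807, 0.903 and 0.903). The call of chromosome 17 ended without tNT line 2, 5 or 6 or NT line 2 (adjusted p = 0.0717, 0.0567, 0.0746 and 0.0576), and that of the X chromosome without tNT line 1, 5 or 6 or NT line 2 (adjusted p = 0.122, 0.0950, 0.114 and 0.117), with its median at 0.06 without tNT line 1 and at 0.06 without NT line 2. Without genes of the shifted chromosomes, an alternative chosen after the data were seen, 113 genes passed between tNT and NT lines, 108 of them shared with the 164.

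**Figure D3:**
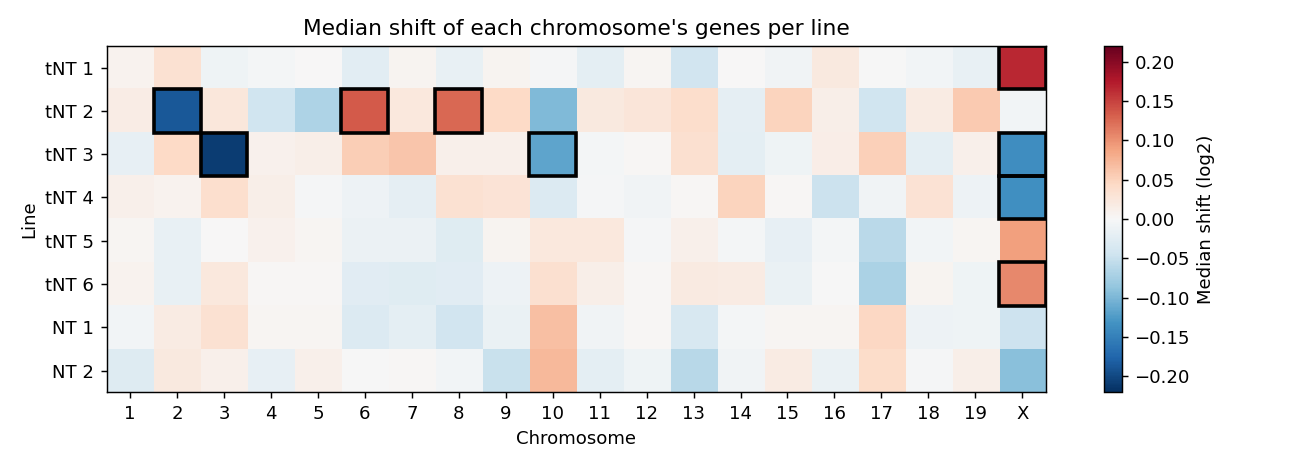
Median log2 shift (colour scale) of the genes of each chromosome (horizontal axis) in each of the 8 lines (vertical axis), with black frames around the 9 called pairs. The lowest value is -0.21 for chromosome 3 in tNT line 3.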

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

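The estimated correlation and the regroupings for chromosomes between groups, which are not used in this part, were chosen after the results were seen. Among 163 sets of values of the 6 tNT lines, 19 had a line far from the others by Dixon's ratio (above 0.625), and 15 of the 19 were line 2. Chance flags about 1 in 20 of independent, normally distributed sets. These sets share the same 6 arrays, and many of the genes were picked by their spread. The number of flags is therefore no test against chance. Line 2 stood apart in its mean correlation with its group (0.973, nearest 0.981), in log2 values of Npas4 (5.60), Thy1 (9.69), Zyx (11.50), Esrrb (12.85) and Nanog (11.97), and in mean deviations of the mitotic spindle checkpoint (-0.13), cholesterol biosynthesis (0.12) and hypoxia and glycolysis lists (-0.30). Its shifts of chromosome 2 (-0.19), chromosome 4 (-0.0436), chromosome 5 (-0.0679), chromosome 12 (0.0269), chromosome 15 (0.0491) and chromosome 19 (0.0571) also stood apart. Line 3 stood apart for chromosome 1 (-0.0175) and chromosome 3 (-0.21), and line 4 for Usp17la (4.80) and chromosome 16 (-0.0481). The shifts of chromosome 12 in line 2 and chromosome 1 in line 3 were not past the random gene lists (adjusted p = 0.169 and 0.175).

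Shifts of whole chromosomes in single lines were weighed against technical explanations. Normalization or background correction as the whole cause is argued against, since over 4 other normalizations the smallest of the 9 shifts was 0.0711 in its called direction, above the bound of 0.05, although without background correction only 3 of the 9 passed. Dim probes are argued against, since the smallest shift among the brighter genes of a chromosome was 0.108. When each chromosome was divided into 4 segments of genes in order, 35 of the 36 segments followed the chromosome's shift, where a segment had to reach 50% of it, and 1 segment of the X chromosome of line 4 did not. A gain or loss of whole chromosomes in part of the cells may account for the pattern, and it stays open because it required all 36 and no karyotype was analysed here.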

How the results depend on the processing

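Choices made after the data were seen were leaving out tNT lines 2 and 3, lines 4 to 6, lines 1 to 3 or the shifted chromosomes, and the estimated correlation for chromosomes. Against 164 genes between tNT and NT lines, 4 other normalizations gave 118 to 242. Array weights gave 1381, leaving out a line 6 to 582, lines at passage 17 to 19 27, and leaving out lines 2 and 3 631, lines 4 to 6 50 and lines 1 to 3 1044. The lowest counts came from leaving out an NT line, a fit in which the lone NT line is assumed to vary like the tNT lines. The cause of these and the other changes was not tested. The NT and tNT lines share the numbers 1 and 2, and their deviations correlated by 0.04 and 0.00. The deviations of 2 NT lines from their mean mirror each other, so these values cannot tell whether the numbers pair the lines. Line number as a replicate block gave 157 genes, 88 of them among the 164. In that fit tNT lines 3 to 6 have no NT line of their number, so only tNT lines 1 and 2 were set against the NT lines. Its model leaves hardly any residual spread per gene, so the count rests mostly on the variance that eBayes shares between genes. For passage, array weights gave 2 genes and every other alternative 0.

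The 7 lists shifted between groups became 0 with an estimated correlation and 5 to 10 otherwise, with 5 for genes detected on all arrays, where the mesoderm list had too few members to be tested. Without genes of the shifted chromosomes, the X chromosome among them, the germ line list has no test result. Without background correction the medians of the primed epiblast, mesoderm, 2-cell-like, trophoblast and germ line lists moved to -0.43, -0.42, 0.50, -0.20 and 0.49, and the primed epiblast median moved to -0.35 with genes detected on all arrays and to -0.37 without tNT lines 4 to 6. The trophoblast median was -0.17 with genes detected on all arrays, -0.25 without tNT lines 2 and 3, -0.23 without lines 1 to 3 and -0.58 without lines 4 to 6. The hypoxia and glycolysis median was 0.38 without lines 2 and 3, 0.37 without lines 1 to 3, 0.41 without the shifted chromosomes and 0.17 without lines 4 to 6. The 2 lists shifted with passage became 0 with an estimated correlation, 0 by fry, 1 with the authors' values, 1 with genes detected on all arrays, and 1 to 4 when a line was left out. The median slope of the fibroblast list was -0.02 without background correction and -0.05 with the authors' values. That of the primed epiblast list was -0.01 and -0.04. The difference in similarity of 0.00572 became 0.00786 with the authors' values and 0.00765 by Spearman, both past the threshold (exact one-sided p = 0.0357), and 0.00382 to 0.00578 under the others. The 3 chromosomes shifted between groups became 0 with an estimated correlation and 1 to 4 when a line was left out. The medians of chromosomes 10, 17 and X were -0.08, -0.05 and 0.07 without background correction, and -0.07, -0.10 and 0.15 without tNT lines 2 and 3. The 9 chromosome shifts of single lines became 3 without background correction and 7 to 12 otherwise. The spread ratio was 1.60 to 1.68. Of 2309 values of named genes under alternatives, 204 lost the call, 122 gained it and 0 reversed. A change of sign counted as reversed only where the value passed the threshold in the main fit or the alternative. Other changes of sign are not in this count. Between 10449 and 10969 probes were above background per array, and genes above it on fewer than 2 arrays were not tested.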

Other observations

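The counts over regroupings of the arrays, the test of other probes for tNT lines 4 to 6, and the test of other probes with each gene counted once, were chosen after the results were seen. The genes higher and lower in tNT lines were weighed against technical explanations. Only the real split of the 28 gave as many as 164 genes, and the highest other gave 0. This argues against chance for the gene count but cannot exclude it. A share of 1 in 28 is the smallest that these splits can give. For lists, 1 of the 28 splits, the real one, gave as many as 7 and the highest other gave 6. The same splits gave at most 6 against 7 to 10 under 4 other normalizations and 0 against 8 by fry. The real split thus led under these settings, in part narrowly, and chance is not excluded for the same reason. The real split did not lead with genes detected on all 8 arrays, where 3 of 28 splits gave as many as 5 of 19 lists. With an estimated correlation no split gave any list. For chromosomes, 17 of 28 gave as many as 3, the highest 8, so chance is not excluded. For passage, 42 of 100 orders gave as many as 391 genes at an unadjusted p under 0.05, the highest 1751, which points to a structure among the tNT lines, and 47 of 100 gave as many as 2 lists, the highest 6, so chance is excluded for neither. In the 164 genes the change over the tNT range of 12 passages had a median of -0.231% of the group difference (quartiles -15.0% and 20.7%). This cannot decide on a passage difference as the cause. Genes past the threshold were picked for a small spread among tNT lines, which limits their slopes. Passage stays open, also because NT passages are not given. Variants under single probes are argued against as a set for the 29 of the 164 genes with another detected probe, since 35 of 37 other probes had the sign of the gene, at a median of 75.3% of its difference, and stay open for the rest. Exceptions were Gm5662 and Arhgef25, with another probe of opposite sign, and Ghr, where the other probe had 1.23% of the difference. In the fit of every probe, which called 164 probes and counts some genes in both directions, the median was 73.8%, and a called probe of Zfp330 differed by 5.06 where the brightest probe of that gene differed by 0.24. Ploidy, the difference that the design names, stays among the open explanations, as untested, and so does strain.

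Lines 4 to 6 stood apart from the other arrays in 25 genes on 12 chromosomes, with a gap of at least 1 on the log2 scale, and all 25 have a single detected probe. At that gap tNT line 2 alone stood apart in 32 genes and the NT lines in 23. Over all detected probes, 5 dividing probes had another probe of the same gene, and 20% of these, 1 of 5, divided the arrays the same way. That was the probe of Pmaip1, while those of Arl3, 1700123O20Rik, Ercc8 and Fgfr1op2 did not. A difference in strain that alters single probes or transcripts may account for part of the pattern, and the 5 are too few to tell. An array batch is argued against, since the correlation of 10000 undetected probes within lines 4 to 6 ranked 34 among the 56 choices of 3 arrays.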
